A study of Rattus norvegicus with 9 samples.

How the data were processed

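Gene expression was measured by RNA sequencing in 9 rat spleen samples, 3 in each of 3 groups: control, TAA and TAA with celecoxib. TAA is thioacetamide, a liver toxin used to produce cirrhosis in rodents, and celecoxib is an inhibitor of cyclooxygenase 2, the enzyme encoded by Ptgs2. Per the labels, TAA was injected intraperitoneally at 200 mg/kg every 3 days for 8 weeks and then at 100 mg/kg for 8 weeks, and celecoxib was given at 20 mg/kg/day for 8 weeks. Per the labels' protocols, RNA was isolated with TRIzol from spleen and libraries were prepared with standard Illumina protocols. The labels also carry the cell type name splenocytes. They do not state that each sample came from a separate animal, so the p-values measure differences against the spread between these samples.

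The authors deposited raw read counts per gene, whole numbers that sum to a different total in each library. The authors also deposited FPKM values, a unit scaled by gene length and library. Each deposited FPKM equals the count divided by the gene length and by a constant of the library, and that constant was 0.955 to 1.05 times the library's count total. Per the submitters' processing notes, HISAT2 2.0.5 and the build mRatBN7.2 were used. The counting tool, annotation release and strand setting are not given in the sources used here. The coordinates in the files run to 282724300 on chromosome 1 and carry unplaced scaffold names that are not those of mRatBN7.2, so coordinates are printed as the files give them and their build is unresolved. Because strand is not stated, overlapping and antisense genes could share reads, and near-identical gene copies could split them.

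The files hold 34408 gene entries for 9 libraries. Of these, 32883 have rat Ensembl identifiers and 1525 are unnamed gene models, which held 1.43% to 1.77% of the counts. Gene symbols were taken from the files themselves. Totals were 14211789 to 19014761 counts per library, so that 1 count equalled 0.0526 to 0.0704 CPM (counts scaled to a common library total). The spread between libraries exceeded counting error: chi-square per degree of freedom between pairs of libraries was 17.5 to 136 over 36 pairs.

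The main test was edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood fit of all 9 libraries by group, TMM normalization and the default filterByExpr filter (minimum count 10, total 15), which left 15954 genes. All tests were 2-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Common biological variation was a coefficient of 0.311. CPM values were computed with TMM library sizes, and each mean is given with its SD over 3 libraries. There are 10 splits of 3 against 3 libraries, so an exact permutation test of them cannot go below p = 0.1.

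Before the data were examined, the tests, the alternative settings, the rule for named genes and 30 gene lists with 491 members were written down. The lists covered cell types of the spleen and its neighbours and processes tied to TAA, cirrhosis or cyclooxygenase. Each list with at least 4 tested members, 29 in all, was tested against the other genes with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2) and adjusted over the lists. Camera was repeated with a correlation estimated for each list, and fry tested whether a list's genes moved, on balance, one way. A list score is the mean log2 CPM of its tested members in a library. The plan counted members past the threshold over all genes tested, and as edgeR called 0 genes, every list had 0 such members. Members were also counted with p-values adjusted over the list alone. Those counts are not adjusted for the number of lists or comparisons, so they describe lists and are not calls.

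The rule named up to 12 genes with the largest rise and 12 with the largest fall among genes past the threshold whose groups did not overlap, and as none passed, 0 genes came from that part. It further named the 4 members of each list with the smallest p in each comparison, Ptgs1 and Ptgs2, and up to 12 genes called in opposite directions in both TAA comparisons. Genes named outside the rule are marked in the text as chosen after their values were seen.

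The position of a library between control and TAA was taken on the 500 genes with the smallest p between the controls and all TAA libraries but 1, where 0 is the control mean and 1 the mean of the TAA libraries kept. The TAA library left out was placed the same way. Because both TAA comparisons share the 3 TAA libraries, opposite changes were also counted in simulated unchanged groups.

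The gene and list tests were tested on simulated data. For TAA against control with 200 changed genes, edgeR called 12.5% of those changed 2-fold among 15723 genes. It called 80.5% of those changed 4-fold among 15714 genes and 92.5% of those changed 8-fold among 15754 genes. DESeq2 1.42.0 called 52.5%, 91.0% and 93.5% of these among 15954 genes. It made 50, 55 and 53 false calls, where edgeR had 2, 11 and 16. With the T cell list lowered 1.5-fold and genes drawn independently, camera called that list and 0 others. In the data, correlations estimated for the lists reached 0.888. The list simulation therefore does not show how often camera with its preset correlation calls unchanged lists here.

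The alternative settings chosen before the data were examined were the RLE normalization, no filter or a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, the deposited FPKM on log2(FPKM + 1) with and without a filter or log2(FPKM + 0.1), only the groups compared, the replicate number as a block, immunoglobulin and haemoglobin genes left out, stricter thresholds, camera on ranks, 100 or 2000 genes for the position and leaving out each library in turn. The labels give all groups replicate numbers 1 to 3 and do not say what a number marks. Correlations of the deviations of same-numbered libraries were 0.178 to 0.475 between control and TAA+celecoxib, all over 0.1. The numbers could mark pairs there, but so few correlations cannot show it. The highest was between control 1 and TAA+celecoxib 1, which both stood apart from the other libraries in the Results. Such correlations were -0.021 to 0.240 between control and TAA and -0.213 to 0.120 between TAA and TAA+celecoxib. The main fit was unpaired in every comparison, with the block as an alternative. Alternatives chosen after seeing the data left out control 1 and TAA+celecoxib 1 together, used edgeR's other dispersion fit or voom with sample weights, and recomputed the position without single control or TAA+celecoxib libraries. The hepatocyte list had 2 tested members and was not tested as a list.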

Results

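Spleen RNA was compared between control rats, rats given TAA and rats given TAA with celecoxib, in 3 libraries per group. The control libraries held 16848246, 17530220 and 16657664 counts, the TAA libraries 14429359, 14211789 and 19014761, and the TAA+celecoxib libraries 16672254, 14887149 and 17072321. Mitochondrial genes took 3.15% to 4.60% of the counts, immunoglobulin genes 2.61% to 5.69% and haemoglobin genes 0.840% to 5.35%.

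Cell type markers varied within groups as well as between them. Control 1 and TAA+celecoxib 1 stood apart on the first principal component, which held 31.3% of the variance, at -63.2 and -60.3, while the other 7 libraries lay between -1.73 and 50.1. Their macrophage scores were 6.72 and 6.33 on the log2 CPM scale and their endothelium scores 4.31 and 4.21, whereas no other library was below 7.63 and 5.16. Erythroid scores were highest in TAA+celecoxib 2 (7.96) and TAA 1 (7.88). Transcripts of hepatocytes were found in TAA 1, with Alb, which encodes albumin, at 575 CPM, and in control 1 at 89.0 CPM, while the other 7 libraries had at most 0.701 CPM.

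**Figure D1:**
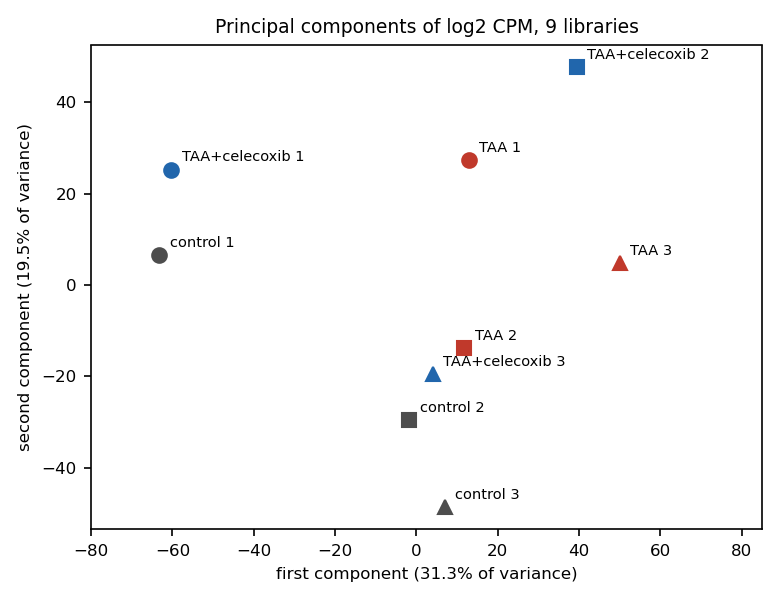
First against second principal component of log2 CPM for the 9 libraries, coloured by group and shaped by replicate number (circle 1, square 2, triangle 3). Control 1 and TAA+celecoxib 1 lie at -63.2 and -60.3 on the first component, and the 3 libraries of each group are spread over the plane.

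The first comparison, TAA against control, asks how TAA treatment changed the spleen. Genes of neutrophils and their precursors rose as a group in the TAA spleens, and so did genes of erythroid cells, megakaryocytes, lipoxygenases and cell division, while genes of T cells, NK cells and the interferon response fell. None of these calls held with an estimated correlation (adjusted p = 0.416, and 0.474 for cell division). All 17 genes of neutrophils and granulocyte precursors had higher fitted values in TAA, with a median log2 fold change of 2.22 (camera adjusted p = 7.03e-14; adjusted p = 0.416 with an estimated correlation), and 11 of them were higher when adjusted over the list alone. Camp, an antimicrobial peptide of neutrophil granules (ENSRNOG00000020733, chromosome 8, 117930546 to 117932518), was at 33.2 ± 13.9 CPM (SD, n = 3) in TAA and 7.24 ± 1.73 CPM in control. Elane, the elastase of granulocyte precursors, was at 27.1 ± 27.9 CPM in TAA and 2.16 ± 1.23 CPM in control, and Ctsg, a protease of the same granules, at 39.0 ± 34.2 and 3.56 ± 1.30 CPM. The neutrophil score was 4.54, 4.46 and 6.41 in the TAA libraries and 1.95, 3.61 and 3.30 in the controls.

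Of the 25 erythroid genes, 24 were higher, with a median log2 fold change of 1.61 (camera adjusted p = 5.52e-09; adjusted p = 0.416 with an estimated correlation) and 0 members past the threshold when adjusted over the list alone. Slc4a1, the anion exchanger of red cells, was at 812 ± 749 CPM in TAA and 117 ± 125 CPM in control, and Sptb, a spectrin of the red cell membrane, at 255 ± 215 and 40.5 ± 29.1 CPM. The erythroid score differed by 1.86, and by 1.20 without TAA 1. Erythroid scores of the groups overlapped, at 5.38 in TAA 2 and 5.76 in control 1. All 26 cell cycle genes were higher, with a median log2 fold change of 0.67 (camera adjusted p = 2.06e-06; adjusted p = 0.474 with an estimated correlation). Mki67, a marker of dividing cells, was at 316 ± 150 CPM against 134 ± 66.0 CPM, and the score difference of 0.57 became 0.33 without TAA 1. Cell cycle scores overlapped too, at 5.29 in TAA 3 and 5.67 in control 1. The megakaryocyte and platelet list had a median of 0.68 (camera adjusted p = 1.41e-05; adjusted p = 0.416 with an estimated correlation). Its members Itga2b, a platelet integrin, and Ppbp, a platelet chemokine, were at 102 ± 7.54 and 32.7 ± 4.27 CPM in TAA and at 61.1 ± 19.7 and 15.7 ± 7.41 CPM in control, and the score difference of 0.67 became 0.35 without control 1. The leukotriene and lipoxygenase list had a median of 0.57 (camera adjusted p = 0.00568; adjusted p = 0.416 with an estimated correlation), led by Alox15 at 51.4 ± 20.7 CPM against 14.5 ± 2.53 CPM.

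T cell genes fell: 17 of 18 were lower, with a median log2 fold change of -0.72 (camera adjusted p = 1.07e-11; adjusted p = 0.416 with an estimated correlation). When adjusted over the list alone 14 were lower, among them Cd3e, Cd247, Lck and Zap70 of T cell receptor signalling. Cd8a, a chain of the CD8 co-receptor (ENSRNOG00000007178, chromosome 4, 99239115 to 99243351), was at 46.1 ± 8.52 CPM in TAA and 85.5 ± 9.32 CPM in control, and Cd8b at 11.4 ± 3.18 and 20.5 ± 3.66 CPM. The B cell list did not pass, with a median of -0.12 (camera adjusted p = 0.377). NK and cytotoxic genes fell too, with a median of -0.45 (camera adjusted p = 0.000398; adjusted p = 0.416 with an estimated correlation), and 1 of 13, Klrd1, was lower when adjusted over the list alone. Klrd1, an NK receptor subunit, was at 12.8 ± 0.885 CPM in TAA and 27.0 ± 4.60 CPM in control. Interferon response genes had a median of -0.32, with 19 of 22 lower (camera adjusted p = 0.000398; adjusted p = 0.416 with an estimated correlation), and Mx2 was at 98.5 ± 11.1 CPM against 176 ± 39.7 CPM. The interferon score difference was -0.25, and -0.14 without control 2, the control with the highest score.

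A further 9 lists passed camera's threshold, each with a call that ended when a certain library was left out. Macrophage genes had a median of 0.63, with all 16 higher (camera adjusted p = 0.000189; adjusted p = 0.454 with an estimated correlation). Their score difference of 0.59 became 0.27 (adjusted p = 0.0505) without control 1, the control with the low macrophage score. Siglec1, a macrophage lectin, was at 404 ± 83.4 CPM in TAA and 237 ± 44.2 CPM in control. Haem and iron recycling genes (median 0.50, camera adjusted p = 0.000398) had adjusted p = 0.0544 without control 1, and their mean log2 fold change of 0.77 includes Hpx, a liver product chosen after its values were seen, at 71.0 CPM in TAA 1 with its hepatocyte transcripts. Mast cell, eosinophil and basophil genes (median 0.75, camera adjusted p = 0.00801) had 0.0505 without control 1. Regulatory and checkpoint T cell genes (median -0.40, camera adjusted p = 0.00568) went from a score difference of -0.33 to -0.12 (0.242) without control 1. With an estimated correlation, adjusted p = 0.416 for these 3 lists. Cpa3 and Mcpt1, proteases of mast cells, were at 6.58 ± 3.04 and 13.2 ± 2.89 CPM in TAA and at 0.990 ± 0.419 and 2.87 ± 0.397 CPM in control, and both were higher when adjusted over the list alone. Tnfrsf18, a receptor of regulatory T cells, was at 8.59 ± 0.794 against 14.4 ± 1.78 CPM and was lower when adjusted over the list alone.

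NRF2 target genes of oxidative stress (median 0.31, camera adjusted p = 0.00801) went from a score difference of 0.25 to 0.12 (adjusted p = 0.133) without control 1 and 0.15 (0.109) without TAA 1. Dendritic cell genes (median -0.38, camera adjusted p = 0.00568) had 0.0632 without TAA 1, and Xcr1, a receptor of cross-presenting dendritic cells, was at 20.6 ± 1.35 CPM against 36.2 ± 10.3 CPM. Heat shock genes (median -0.61, camera adjusted p = 0.000844) went from a score difference of -0.50 to -0.14 (0.211) without control 2. Pancreatic acinar genes (median 0.92, camera adjusted p = 0.0239) had adjusted p = 0.171, 0.0876 and 0.691 without control 1, control 2 and TAA 2. For acinar genes the score difference of 0.77 became 0.18 without TAA 2, 1.45 without TAA 1 and 1.44 without TAA 3. With an estimated correlation, adjusted p = 0.416 for these 4 lists. Plasma cell genes (median 0.17, camera adjusted p = 0.0219; adjusted p = 0.506 with an estimated correlation) had 0.231, 0.219, 0.0837 and 0.158 without control 2, control 3, TAA 1 and TAA 2. For plasma cell genes it went from 0.21 to 0.12 without control 2, 0.13 without control 3 and 0.37 without control 1.

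Beside the B cell list, 11 lists did not pass in this comparison. Extracellular matrix genes had a median of 0.05 (camera adjusted p = 0.214), endothelial genes 0.26 (0.204), smooth muscle genes -0.06 (0.374) and white pulp chemokine and stroma genes -0.20 (0.647). Prostaglandin genes had a median of 0.07 (0.633), inflammatory cytokine genes -0.16 (0.0605), MHC class II genes -0.06 (0.717), unfolded protein response genes 0.05 (0.673) and immediate early genes 0.10 (0.913). Adipocyte and mesothelium genes, which mark neighbouring tissue, had medians of 0.19 (0.673) and -0.32 (0.982). The median was negative and the mean positive for MHC class II genes, and the camera direction was down with a positive median for immediate early genes. Dcn, the matrix proteoglycan decorin (ENSRNOG00000004554, chromosome 7, 38742051 to 38782323), was at 6.88 ± 0.384 CPM in TAA and 2.76 ± 0.145 CPM in control, and was the only matrix gene past the threshold when adjusted over the list alone.

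At the level of single genes, edgeR called 0 of 15954 genes in TAA against control (smallest adjusted p 0.325). It found 957 at an unadjusted p under 0.05, where 798 are expected by chance if genes are independent. Another split of the same libraries, control 1, TAA 1 and TAA 2 against the rest, gave 1101, so 957 shows no excess tied to the groups. Limma-voom called 0, with 861 at an unadjusted p under 0.05, and DESeq2 called 50, of which 28 were higher and 22 lower. In 20 simulated sets with no change, DESeq2 called a mean of 19.9 genes and at most 35. The libraries of the groups did not overlap in 14.8% of genes, where chance gives 10%. Without TAA+celecoxib 2, edgeR called 1 gene, LOC100911575. Among the DESeq2 calls, chosen after their values were seen, were Defa5 and RatNP-3b, defensins of granulocytes, at 115 ± 95.6 and 73.3 ± 61.3 CPM in TAA and 13.3 ± 1.99 and 7.31 ± 2.61 CPM in control. Asb2, part of a ubiquitin ligase, was at 18.2 ± 2.02 CPM in TAA and 36.2 ± 1.80 CPM in control, and Col6a5, a collagen chain, at 157 ± 35.6 and 294 ± 33.9 CPM.

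**Figure D2:**
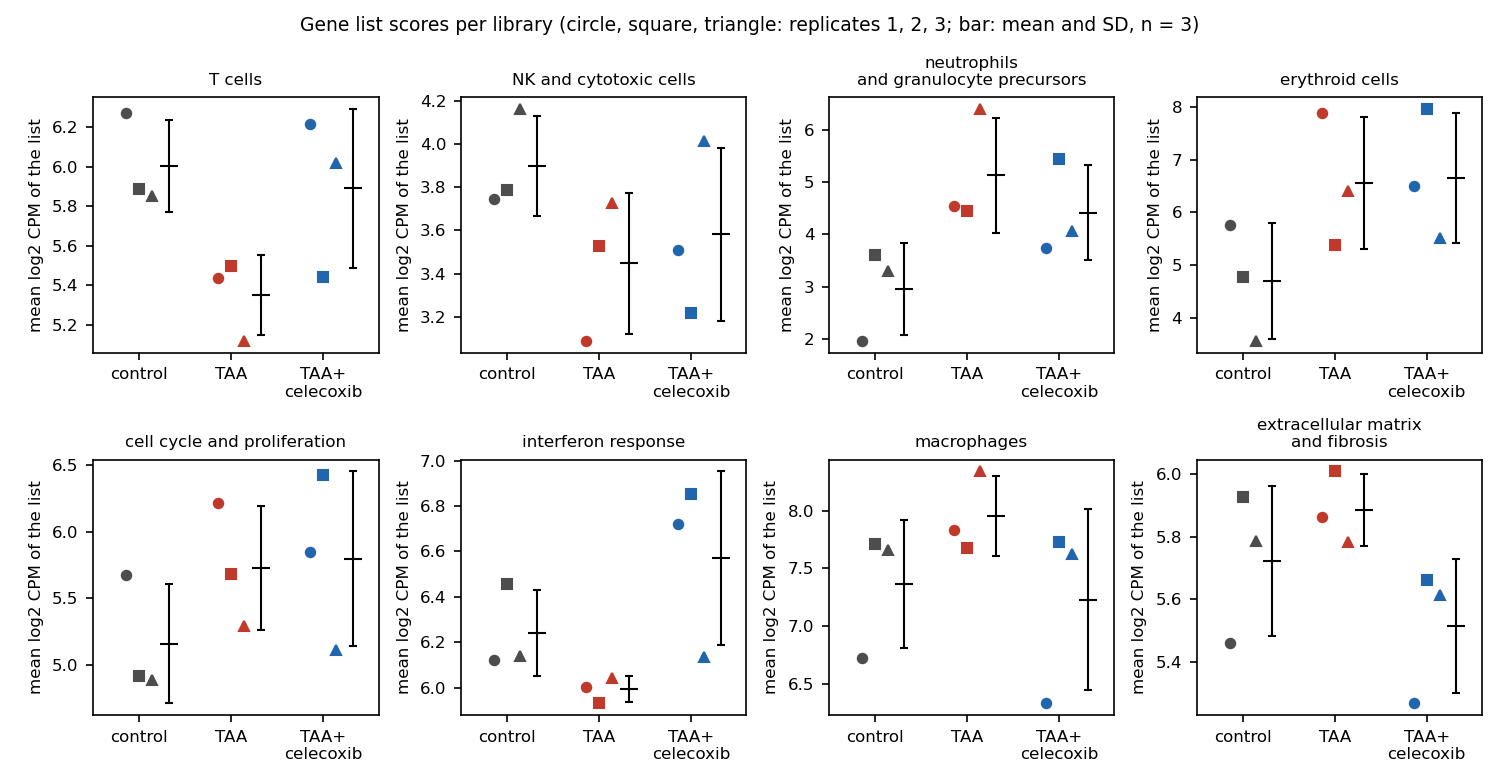
Mean log2 CPM of the members of 8 gene lists in each library, by group, with the mean and SD of 3 libraries as a bar; the vertical axes do not start at 0. The 3 TAA libraries lie below all controls in T cell and NK genes and above all controls in neutrophil genes, and the macrophage score is low in control 1 (6.72) and TAA+celecoxib 1 (6.33).

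The second comparison, TAA+celecoxib against TAA, asks what celecoxib changed in rats given TAA. Interferon response and T cell genes rose in the TAA+celecoxib spleens, and macrophage and extracellular matrix genes fell. None of these calls held with an estimated correlation (adjusted p = 0.526, and 0.633 for macrophages). Of 22 interferon response genes, 20 were higher, with a median log2 fold change of 0.65 (camera adjusted p = 4.89e-10; adjusted p = 0.526 with an estimated correlation), and 12 were higher when adjusted over the list alone, including Isg15, Irf9 and Usp18. Mx2, an antiviral GTPase, was at 267 ± 125 CPM (SD, n = 3) in TAA+celecoxib and 98.5 ± 11.1 CPM in TAA, Mx1 at 470 ± 208 and 229 ± 5.22 CPM, and Herc6 at 88.2 ± 37.0 and 36.7 ± 5.44 CPM. The interferon score was 6.72, 6.85 and 6.14 in the TAA+celecoxib libraries and 5.93 to 6.04 in the TAA libraries.

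T cell genes were higher for 17 of 18 members, with a median log2 fold change of 0.63 (camera adjusted p = 1.09e-09; adjusted p = 0.526 with an estimated correlation). Cd8a and Cd8b were higher when adjusted over the list alone: Cd8a was at 92.1 ± 1.06 CPM in TAA+celecoxib and 46.1 ± 8.52 CPM in TAA, and Cd8b at 20.7 ± 2.82 and 11.4 ± 3.18 CPM. The T cell score of TAA+celecoxib 2, 5.44, lay within the range of the TAA libraries. Macrophage genes were lower for 15 of 16 members, with a median of -0.64 (camera adjusted p = 9.24e-06; adjusted p = 0.633 with an estimated correlation). C1qa and C1qc, chains of complement C1q made by macrophages, were at 568 ± 121 and 547 ± 218 CPM in TAA+celecoxib and at 956 ± 12.5 and 1147 ± 207 CPM in TAA. The macrophage score difference was -0.72, and -0.27 without TAA+celecoxib 1, which had the lowest macrophage score. Matrix genes were lower for 23 of 28 members, with a median of -0.27 (camera adjusted p = 0.000133; adjusted p = 0.526 with an estimated correlation), and their score difference of -0.37 became -0.25 without TAA+celecoxib 1. Dcn was at 2.07 ± 0.371 CPM against 6.88 ± 0.384 CPM and was lower when adjusted over the list alone. Mmp2, a gelatinase, was at 14.8 ± 3.52 and 24.8 ± 4.52 CPM, and Ccn2, a fibrosis-associated matricellular protein, at 67.7 ± 7.23 and 115 ± 31.7 CPM.

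The other 8 lists past the threshold each lost their call without some library. Haem and iron recycling genes (median -0.53, camera adjusted p = 0.000347) went from a score difference of -0.88 to -0.52 (adjusted p = 0.113) without TAA+celecoxib 1, and megakaryocyte genes (median -0.38, camera adjusted p = 0.00744) from -0.39 to -0.19 (0.311). The mean log2 fold change of the haem list was -1.03 and includes Hpx, made by the liver. Hpx moved with the hepatocyte transcripts, at 71.0 CPM in TAA 1 (Alb 575 CPM) and at most 0.685 CPM in the other TAA libraries. Hp, also made by the liver, was at 107 CPM in TAA 1, 12.7 CPM in TAA 2 and 64.4 CPM in TAA 3. Endothelial genes (median -0.45, camera adjusted p = 0.00768) had 0.127 without TAA 3, and their score difference of -0.47 became -0.14 (0.552) without TAA+celecoxib 1. Regulatory and checkpoint T cell genes (median 0.40, camera adjusted p = 0.00512) had 0.0848 without TAA 3, and their score difference of 0.33 became 0.16 (0.113) without TAA+celecoxib 1 and 0.50 without TAA+celecoxib 2. With an estimated correlation, adjusted p = 0.633 for these 4 lists. Lag3, an inhibitory receptor of T cells, was at 23.6 ± 3.47 CPM against 15.7 ± 2.79 CPM. Mast cell, eosinophil and basophil genes (median -0.74, camera adjusted p = 0.00744; adjusted p = 0.526 with an estimated correlation) had 0.0518 without TAA 3. Mcpt1 was at 4.27 ± 3.23 CPM against 13.2 ± 2.89 CPM, and with Cpa3 it was lower when adjusted over the list alone.

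Unfolded protein response genes (median -0.21, camera adjusted p = 0.00990; adjusted p = 0.633 with an estimated correlation) went from a score difference of -0.16 to -0.10 (adjusted p = 0.149) without TAA 2 and had 0.159 without TAA+celecoxib 3. Sdf2l1, an endoplasmic reticulum cofactor, was at 84.3 ± 4.64 CPM against 133 ± 35.7 CPM. Neutrophil genes (median -0.98, camera adjusted p = 0.00498; adjusted p = 0.633 with an estimated correlation) had 0.676, 0.151 and 0.0921 without TAA 3, TAA+celecoxib 1 and TAA+celecoxib 3. The neutrophil score difference of -0.72 became -0.08 without TAA 3, -0.38 without TAA+celecoxib 1 and -1.23 without TAA+celecoxib 2. B cell genes (median 0.30, camera adjusted p = 0.0282; adjusted p = 0.658 with an estimated correlation) had 0.401, 0.890 and 0.230 without TAA 3, TAA+celecoxib 1 and TAA+celecoxib 3. Their score difference of 0.19 became 0.07 without TAA 3, -0.0048 without TAA+celecoxib 1 and 0.44 without TAA+celecoxib 2.

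The 17 lists that did not pass had camera adjusted p-values of 0.0596 or more, among them cell cycle genes (median 0.13), erythroid genes (0.27), NK and cytotoxic genes (0.26), plasma cell genes (-0.08) and heat shock genes (-0.02). For 4 of these lists the median, the mean and the camera direction differed in sign. When adjusted over the list alone, Klrd1 was higher, at 19.1 to 21.3 CPM in TAA+celecoxib and 11.9 to 13.7 CPM in TAA, and Fkbp11 of the plasma cell list was lower.

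By edgeR, 0 of 15954 genes were called between TAA+celecoxib and TAA (smallest adjusted p 0.328), with 812 at an unadjusted p under 0.05. Limma-voom called 0, with 741 at an unadjusted p under 0.05. DESeq2 called 22 genes, 9 higher and 13 lower, where simulated sets with no change gave a mean of 19.2 and at most 37. Groups did not overlap in 10.9% of genes, where chance gives 10%. Without TAA 1, edgeR called 3 genes, Fabp5, LOC103689983 and Rpl35al1. The DESeq2 calls, chosen after their values were seen, included Tlr3, a sensor of double-stranded RNA, at 55.4 ± 4.73 CPM in TAA+celecoxib and 35.5 ± 2.56 CPM in TAA. Zbp1, an interferon-induced nucleic acid sensor, was at 65.9 ± 33.6 and 26.6 ± 1.92 CPM, and Themis, needed for thymocyte selection, at 12.9 ± 1.84 and 7.24 ± 0.234 CPM.

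**Figure D3:**
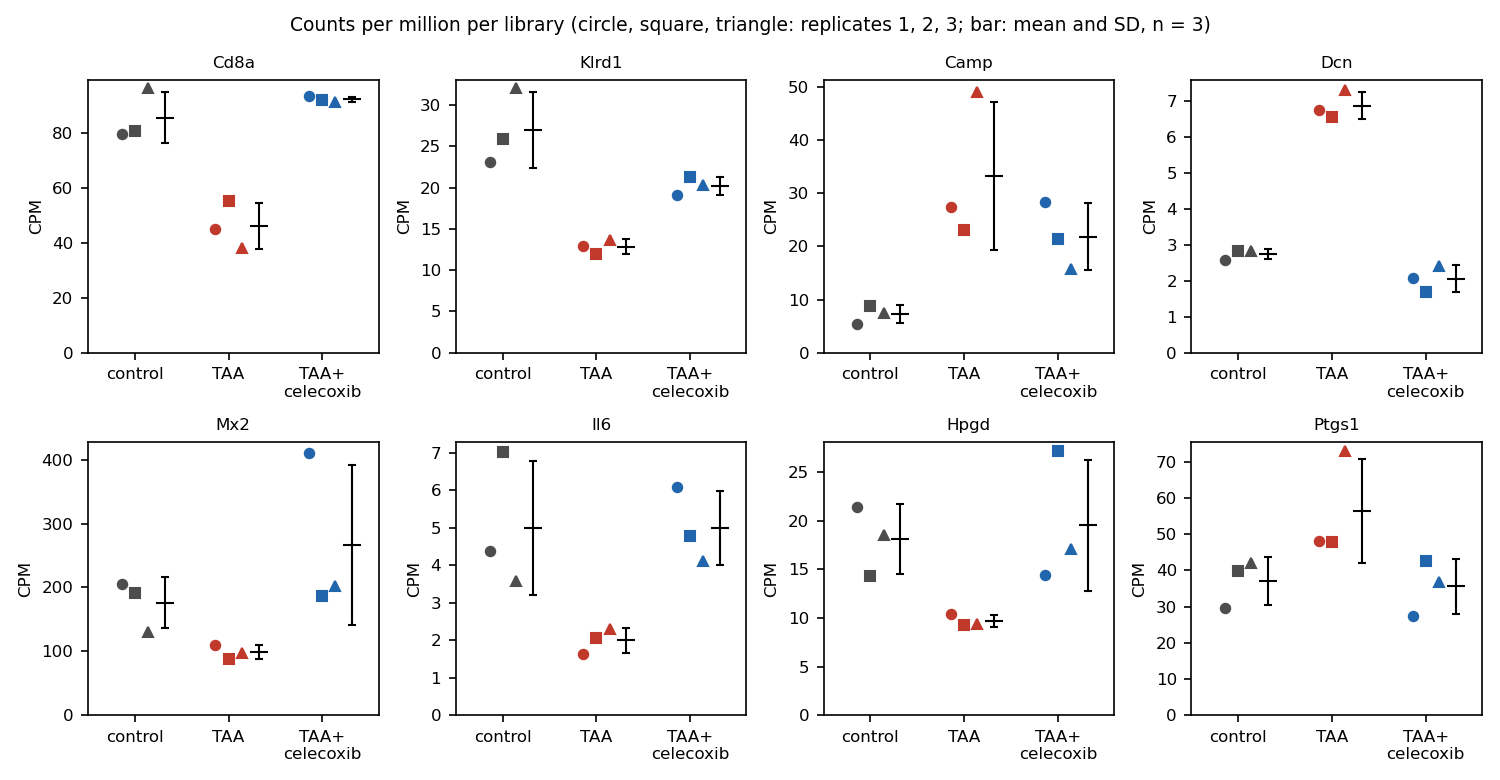
CPM of 8 genes in each library, by group, with the mean and SD of 3 libraries as a bar; each axis starts at 0. Cd8a and Dcn of TAA+celecoxib lie near control (92.1 against 85.5 CPM and 2.07 against 2.76 CPM), while Camp stays above control in all TAA+celecoxib libraries.

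Prostaglandin genes include the target of celecoxib. Ptgs2 (ENSRNOG00000002525, chromosome 13, 67351087 to 67359335) was low in the spleen, where 3 counts equal 0.158 to 0.211 CPM, at 1.05 ± 0.144 CPM in control, 0.905 ± 0.315 CPM in TAA and 1.20 ± 0.437 CPM in TAA+celecoxib. Ptgs1, which encodes cyclooxygenase 1 (ENSRNOG00000007415, chromosome 3, 15560712 to 15582344), was at 37.2 ± 6.64, 56.4 ± 14.5 and 35.6 ± 7.66 CPM. Its 3 TAA libraries lay above all controls and all TAA+celecoxib libraries, but edgeR's adjusted p was 0.788 against control and 0.890 for TAA+celecoxib against TAA. Hpgd, the enzyme that inactivates prostaglandins, was at 18.1 ± 3.60 CPM in control, 9.72 ± 0.629 CPM in TAA and 19.6 ± 6.74 CPM in TAA+celecoxib, with edgeR adjusted p-values of 0.788 and 0.890 as well. Il6, an inflammatory cytokine, was at 3.59 to 7.01 CPM in control, 1.63 to 2.30 CPM in TAA and 4.12 to 6.08 CPM in TAA+celecoxib, likewise with no call.

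The comparison of TAA+celecoxib with control asks what remained different under both compounds. Erythroid, cell cycle and neutrophil genes had higher group means than control, though none of these calls held with an estimated correlation (adjusted p = 0.640). Only the neutrophil scores did not overlap between the groups. TAA+celecoxib 3 lay below control 1 in the erythroid score (5.52 against 5.76) and the cell cycle score (5.12 against 5.67). For erythroid genes 24 of 25 were higher, with a median log2 fold change of 2.17 (camera adjusted p = 3.45e-12; adjusted p = 0.640 with an estimated correlation). Tal1, a transcription factor of erythroid precursors, was at 134 ± 104 CPM (SD, n = 3) in TAA+celecoxib and 37.3 ± 16.0 CPM in control. All 26 cell cycle genes were higher, with a median of 0.68 (camera adjusted p = 3.99e-09; adjusted p = 0.640 with an estimated correlation), and the score difference of 0.64 became 0.32 without TAA+celecoxib 2 and 0.98 without TAA+celecoxib 3. Neutrophil genes had a median of 1.59 (camera adjusted p = 8.69e-09; adjusted p = 0.640 with an estimated correlation), and 7 of 17 were higher when adjusted over the list alone. Camp was at 21.9 ± 6.32 CPM against 7.24 ± 1.73 CPM, Ngp, a granule protein of neutrophils, at 22.8 to 42.5 CPM against 6.65 ± 5.03 CPM, and Mpo, the myeloperoxidase of precursors, at 90.0 ± 104 against 8.92 ± 4.06 CPM. The neutrophil score difference of 1.47 became 0.96 without control 1 and 0.95 without TAA+celecoxib 2.

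The other 7 lists past the threshold lost their call without 1 or more libraries. Heat shock genes (median -0.49, camera adjusted p = 0.000223) went from a score difference of -0.63 to -0.27 (adjusted p = 0.0977) without control 2. Hspa1b, an inducible HSP70, was at 1.69 ± 0.736 CPM against 21.0 ± 20.7 CPM in control and was lower when adjusted over the list alone. Interferon response genes (median 0.35, camera adjusted p = 0.00331) had 0.0860 without control 3 and 0.380 without TAA+celecoxib 1. The interferon score difference of 0.33 became 0.19 without TAA+celecoxib 2 and 0.55 without TAA+celecoxib 3. Rsad2, the antiviral protein viperin, was at 193 ± 166 CPM against 53.0 ± 22.5 CPM. Matrix genes (median -0.22, camera adjusted p = 0.00824) went from a score difference of -0.21 to -0.11 (0.159) without control 2, -0.09 (0.359) without TAA+celecoxib 1 and -0.34 without control 1. Eln, which encodes elastin, was at 27.3 ± 2.69 CPM against 46.1 ± 11.1 CPM. With an estimated correlation, adjusted p = 0.640 for these 3 lists.

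Dendritic cell genes (median -0.35, camera adjusted p = 0.0273; adjusted p = 0.640 with an estimated correlation) had 0.0977, 0.0529 and 0.120 without control 2, control 3 and TAA+celecoxib 1. Smooth muscle genes (median -0.26, camera adjusted p = 0.0306; adjusted p = 0.640 with an estimated correlation) had 0.223, 0.118, 0.0604 and 0.205 without control 1, control 2, TAA 1 and TAA+celecoxib 1. Their score difference of -0.23 became -0.12 without control 1 and -0.37 without control 3. Unfolded protein response genes (median -0.15, camera adjusted p = 0.0467; adjusted p = 0.754 with an estimated correlation) had 0.304, 0.138, 0.0652, 0.0752 and 0.376 without control 1, control 2, TAA 1, TAA+celecoxib 1 and TAA+celecoxib 3. Their score difference of -0.15 became -0.08 without control 1 and -0.23 without control 3. NK and cytotoxic genes (median -0.30, camera adjusted p = 0.0306; adjusted p = 0.640 with an estimated correlation) kept their call only without TAA+celecoxib 3, where the score difference of -0.32 became -0.53. Without control 1, 2 and 3 they had 0.107, 0.0664 and 0.351, without TAA 1, 2 and 3 0.102, 0.104 and 0.0751, and without TAA+celecoxib 1 and 2 0.377 and 0.226. The score difference was -0.12 without control 3, -0.16 without TAA+celecoxib 1 and -0.13 without TAA+celecoxib 2.

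Among the 19 lists that did not pass (smallest camera adjusted p 0.0761), megakaryocyte and platelet genes (median 0.21, camera adjusted p = 0.0761) passed with the replicate number as a block (adjusted p = 0.0470; adjusted p = 0.820 with an estimated correlation). T cell genes had a median of -0.05 (0.398) and macrophage genes a median of -0.03 (0.678). The median, mean and camera direction differed in sign for 5 of these lists. EdgeR called 0 of 15954 genes between TAA+celecoxib and control (smallest adjusted p 0.566), with 803 at an unadjusted p under 0.05. Limma-voom called 0, with 631 at an unadjusted p under 0.05, and DESeq2 called 26, 15 higher and 11 lower, where simulated sets with no change gave a mean of 16.8 and at most 30. Groups did not overlap in 9.68% of genes, where chance gives 10%. Without TAA 1, edgeR called 2 genes, LOC103689983 and Rpl35al1.

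Whether celecoxib moved genes back towards control was asked in 2 ways. EdgeR called 0 genes in opposite directions in TAA against control and in TAA+celecoxib against TAA, since it called 0 in either (957 and 812 at an unadjusted p under 0.05). Limma-voom called 0 in either as well. DESeq2 called 6 in opposite directions and 0 in the same direction, where 20 simulated sets with no change gave a mean of 3.45 and at most 8. These 6, chosen after their values were seen, were Cd8a, Dcn, Parm1, Usp40, AABR07051533.1 and an unnamed gene model. Parm1 was at 48.6 to 52.3 CPM in control, 28.2 to 33.5 CPM in TAA and 43.2 to 64.9 CPM in TAA+celecoxib, and Usp40, a deubiquitinase, at 48.2 ± 2.05, 32.2 ± 3.45 and 48.4 ± 1.76 CPM. Across genes, which are not independent replicates, the covariance of the fold changes was -0.123, against -0.0991 in simulated unchanged groups that share the TAA libraries, a difference of -0.0236. Of 840 regroupings of the 9 libraries, 207 had a covariance as low. The TAA libraries are too few to be split, so part of the negative covariance comes from sharing them.

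On the 500 genes that best separated control from TAA, the TAA+celecoxib libraries lay at 0.229, 0.829 and 0.307 between the control mean (0) and the TAA mean (1). Their mean was 0.455 ± 0.326 (SD, n = 3), and the TAA libraries left out in turn lay at 0.511 ± 0.157. An exact 2-sided permutation test gave p = 0.8, where the smallest p possible is 0.1. TAA+celecoxib 2, with the highest erythroid score, was the library nearest to TAA. Without it the mean was 0.270 (n = 2), against 0.496 for the left-out TAA libraries (exact permutation p = 0.2). No control was left out, so where a control not used to choose the genes would lie is not known.

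**Figure D4:**
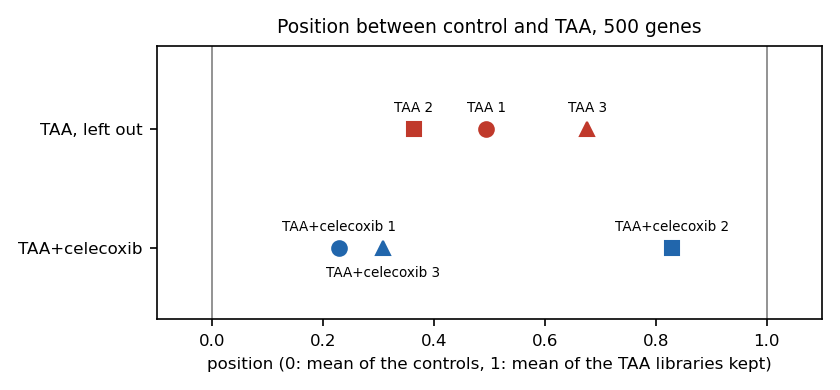
Position of each TAA+celecoxib library and of each TAA library left out in turn, on a scale where 0 is the mean of the controls and 1 the mean of the TAA libraries kept, over 500 genes. The TAA+celecoxib libraries lie at 0.229, 0.307 and 0.829, and the left-out TAA libraries at 0.364, 0.494 and 0.676.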

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

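The alternatives that leave out control 1 and TAA+celecoxib 1 together, refit edgeR's dispersion or weight samples, and the position without single libraries, were chosen after the data were seen. Genes called by edgeR, 0 in each comparison, stayed at 0 under every other alternative but these: DESeq2 called 50 (TAA against control), 22 (TAA+celecoxib against TAA) and 26 (TAA+celecoxib against control) and 6 in opposite directions, and a fit of only the groups compared called 1, Rpl35al1, in TAA+celecoxib against control. Leaving out each library gave 0 to 1, 0 to 3 and 0 to 2 calls, and 0 to 0 in opposite directions. The cause was not tested. The number of lists past the threshold, 17, 12 and 10, became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 by fry. It was 11 to 20, 10 to 19 and 6 to 12 over the libraries left out (11 without control 1 for TAA against control, 19 without TAA+celecoxib 2 for TAA+celecoxib against TAA, and 6 without control 2 or TAA+celecoxib 1 for TAA+celecoxib against control), and 13, 10 and 6 without both libraries apart. Calls held in all 9 leave-outs for 8 of 17, 4 of 12 and 3 of 10 lists. The position was 0.270 to 0.567 over the libraries left out. Fold changes near 0 turned sign in TAA+celecoxib against control: Ptgs1 (-0.06) ranged from -0.21 to 0.095 over the libraries left out and Ptgs2 (0.20) from -0.091 to 0.43. The B cell score difference in TAA+celecoxib against TAA (0.19) ranged from -0.0048 to 0.44. The scalings moved the median of all genes by less than 0.005 log2. Samples share replicate numbers, and same-numbered libraries correlated at 0.178 to 0.475 between control and TAA+celecoxib, but at -0.021 to 0.240 and -0.213 to 0.120 in the other comparisons; 6 of 9 libraries, not every one, correlated best with their own number. With the replicate block edgeR called 0, 0 and 0 genes (1475, 1287 and 1065 at an unadjusted p under 0.05, against 957, 812 and 803 without it). With the block 18, 13 and 11 lists passed: endothelium was added in TAA against control (adjusted p = 0.0202, 0.547 with an estimated correlation), leukotriene genes in TAA+celecoxib against TAA (0.0410, 0.597) and megakaryocytes in TAA+celecoxib against control (0.0470, 0.820). It changed no other call. The spread between samples, a coefficient of 0.311, limits which genes can be called.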

Other observations

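All tests in this part but the counts over other splits were chosen after the results were seen. Some genes of the circadian clock, in no list fixed beforehand, separated control from both TAA groups. They were looked at because some were among the DESeq2 calls, so their number is no test of the clock as a group. Of 15 clock genes, 5 were higher and 2 lower in all 6 TAA and TAA+celecoxib libraries than in all 3 controls. Npas2, a clock activator, was at 9.21 ± 0.957 CPM (SD, n = 3) in control, 3.17 ± 0.461 CPM in TAA and 3.48 ± 1.25 CPM in TAA+celecoxib. Arntl, its relative and core activator, was at 32.2 ± 6.57, 20.1 ± 3.59 and 20.5 ± 3.41 CPM. Nr1d1, a clock repressor, was at 18.9 ± 5.32, 38.0 ± 2.98 and 42.7 ± 12.6 CPM, and Nr1d2, Tef, Per2 and Per3 were also higher in all 6 libraries. DESeq2's adjusted p for Npas2 was 0.000757 in TAA against control and 0.00688 in TAA+celecoxib against control, while edgeR's were 0.725 and 0.911. The labels give no hour of sampling.

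The drop of T cell genes in TAA was set against a loss of lymphocytes in general, which lowers B and T cell genes alike. The T cell score minus the B cell score was -1.92 ± 0.0420 in TAA (SD, n = 3), -1.37 ± 0.118 in control and -1.56 ± 0.0567 in TAA+celecoxib, a difference of -0.55 between TAA and control. The score was made after the T cell list was seen to fall and the B cell list was not. Its difference restates those list differences (-0.65 for T cells and -0.11 for B cells), so it is no independent test of a general loss. As description, the score was lower in TAA than in control by more than the SD of either group. A drop of T cells beyond that of B cells under TAA is a candidate explanation. Tissue counts cannot tell fewer T cells from less mRNA per T cell.

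More blood in the spleen is a candidate explanation for the rise of granulocyte and erythroid genes in TAA. Blood neutrophils largely lack the granule transcripts Mpo, Elane, Prtn3, Ctsg and Ms4a3 of precursors, so blood predicts a rise of mature neutrophil genes at least as large. The precursor score minus the mature score was 1.72 higher in TAA than in control, at -1.34 to -1.07 against -3.26 to -2.32, which argues against blood alone for the granulocyte part. Erythroblast genes also rose more than haemoglobin genes (median log2 fold changes 2.28 and 0.88), a difference of 1.29 in score, but the libraries overlapped and blood stays open for the erythroid part. Granulocyte precursors in the spleen under TAA may underlie the granulocyte part, and no cell counts were used here to check it.

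Control 1 and TAA+celecoxib 1 stood apart from the other 7 libraries. A trend with gene length, as RNA quality would give, is argued against as the whole cause: the 2 libraries had higher values for the shortest genes (median difference 0.19) and lower for the longest (-0.09), but with that trend removed the gap of their macrophage scores to the lowest other library was still -0.93 (before, -0.91). Ribosomal protein genes took 8.72% and 9.27% of counts in these 2 libraries and at most 7.12% in any other. Mitochondrial genes took 4.28% and 4.60% in them and at most 4.07% in any other. Whether RNA quality underlies these shares was not tested. A smaller share of red pulp in the sampled tissue goes with their endothelium scores, whose gap to the lowest other library was -0.85. Their white pulp chemokine scores lay 0.07 above the highest other. Less red pulp could also lower erythroid genes, but the erythroid scores of the 2 libraries were not low. Control 1 had the highest erythroid score of the controls (5.76). TAA+celecoxib 1 lay between the other TAA+celecoxib libraries (5.52 and 7.96). The lists thus differ, and a smaller share of red pulp stays open. As the 2 libraries come from different groups, no biological explanation from the design was tested.

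The counts of calls were repeated over all 10 splits of the 6 libraries of each comparison, too few for a share under 0.05. For lists, 17 passed in TAA against control and at most 16 in another split, so 1 split, the real one, reached it. In TAA+celecoxib against TAA 12 passed and at most 13 elsewhere (3 splits as many), and in TAA+celecoxib against control 10 and at most 12 (5 splits). EdgeR called 0 genes in the real splits and at most 1, 2 and 1 in others. Any split reaches a count of 0, so the edgeR counts cannot tell the real groups from other splits. At an unadjusted p under 0.05, edgeR found 957, 812 and 803 genes in the real splits and at most 1101, 1614 and 2605 in others. For DESeq2 the real counts were 50, 22 and 26 and the highest others 51, 193 and 520, with 2, 6 and 4 splits as large. The 193 calls set TAA 1, TAA 3 and TAA+celecoxib 2 against the rest, the 520 set control 1, TAA+celecoxib 1 and TAA+celecoxib 2 against the rest. Such splits point to a structure of the samples other than the groups. In TAA+celecoxib against control, the counts over all splits ignore any pairing of samples by number, which the labels do not state. The splits that divide every same-numbered pair gave 4, 7 and 18 DESeq2 calls, against 26 in the real split. They gave 12, 8 and 4 lists, against 10 in the real split. These splits are too few for a test.

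The files hold 2 entries named Tnks2, chosen after their values were seen, and reads could be shared between them; their sequences were not compared. One was at 13.3 ± 4.81 CPM (SD, n = 3) in control, 0.542 ± 0.347 CPM in TAA and 0.635 ± 0.405 CPM in TAA+celecoxib, and the other at 3.86 ± 4.83, 20.4 ± 4.97 and 5.62 ± 4.02 CPM. Their sum was 17.1 ± 7.56 CPM in control, 20.9 ± 5.30 CPM in TAA and 6.25 ± 4.04 CPM in TAA+celecoxib. The sums in TAA+celecoxib, 1.80 to 9.68 CPM, overlapped those in control (9.06 to 24.0) and lay below those in TAA (15.1 to 25.5). An exchange of reads between the entries could account for the TAA values against control. Whether it could alone account for those of TAA+celecoxib was not tested.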
